A study of Mus musculus with 53 samples.

How the data were processed

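The series measured 3 histone modifications by chromatin immunoprecipitation and sequencing (ChIP-seq) in 13 mouse cell samples. H3K4me3 and H3K4me2 are methylations of lysine 4 of histone H3 found at active or poised promoters, and H3K27me3 is the methylation of lysine 27 deposited by Polycomb repressive complexes. The cells were the embryonic stem cell (ESC) line R1, 8 induced pluripotent stem cell (iPSC) lines and 4 somatic samples. The somatic samples were mouse embryonic fibroblasts (MEF, 1 sample), adipose progenitor cells (APC, 2 samples) and hematopoietic progenitor cells from bone marrow (HPC, 1 sample). Of 53 samples, 39 were ChIP libraries with a peak list, 13 per mark; the 14 input samples were not analysed here. Per the labels' protocols, chromatin was digested with micrococcal nuclease before immunoprecipitation, and part of the lysate was kept as input. ESC and iPSC were grown with serum and LIF, MEF and APC were cultured, and HPC were taken fresh. Each list was grouped by the cell named in its label, and the number that opens a title (1, 2 or 3) was kept as a title prefix, whose meaning the labels do not state.

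Reads were aligned with Bowtie 0.12.7 to the mouse assembly mm9, per the submitters' processing notes. The peak caller, its settings, the control library used in calling and any filter on reads are not given in the sources used here. Each deposited list held the peaks of 1 library, with edges in steps of 50 bp and no header. A score that never rose down the list stood in the fourth column of all 39 deposited lists, on a scale of its own in each list. It was used to rank peaks within a list and, in 1 alternative setting, for a cut at the median score of all peaks of a mark. That cut compares scores between lists, which their separate scales do not allow for. The fifth column, deposited without a name and ranging from 0.001 to 0.049, was read as a p-value or q-value per peak and was used only to describe the lists. Read counts were not used here, so the depth of each library is unknown and no counting interval can be given. A library sequenced more deeply or enriched more strongly can yield more and longer peaks, and this acts on every measurement below that rests on the number or length of peaks.

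Peaks that overlapped or repeated within a list (at most 3 per library) were merged, and peaks running past a chromosome end (at most 4 per library, by at most 47 bp) were clipped. The genome sequence and GENCODE annotation of NCBIM37, the assembly also called mm9, gave 26048 gene symbols, 22225 of them protein coding and 3823 non-coding; 13 symbols annotated on more than one chromosome, on unplaced sequence or on the mitochondrial genome were dropped. The promoter window of a gene was 2 kb either side of every annotated start, merged, and a gene was marked when a peak covered at least 1 bp of it. The covered percent is the share of window bases under peaks. A gene marked by both H3K4me3 and H3K27me3 in the same cells is called bivalent. The Jaccard index is the number of bases under peaks in both of a pair of lists divided by the number under peaks in either.

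The 8 iPSC lines were compared with the 4 somatic samples, with the ESC value given beside them. Log2 peak number, log2 covered length, Jaccard index, gene counts and list shares were compared by two-sided exact permutation tests over all 495 arrangements, with a smallest possible p of 0.00202. Promoters were called by Fisher's exact test on marked against unmarked libraries, with Benjamini-Hochberg adjustment over the genes marked in 3 to 9 of the 12 libraries and a threshold of 0.05. Similarity to the cell type of origin was the mean own-origin entry of the matrix of lines by somatic types after centring both, and it was tested over all 420 arrangements of the origins. The relation of the Jaccard index with the title prefix was tested over as many arrangements (Spearman's rho and Pearson's r, adjusted by Benjamini-Hochberg over the 3 marks). With 1 ESC library per mark, ESC was set apart only by rank among the 9 pluripotent libraries. The somatic class joins different cell types and the lines differ in origin, so the SD of a class includes those differences. The labels name separate lines but not separate cultures, and p-values measure the spread between these samples. The tests treat the lines as independent, and any descent of a line from another was not taken into account.

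The 16 gene lists were pluripotency, epithelial, germline, hox, neural factors, endoderm mesoderm, mesenchymal, adipogenic, haematopoietic, endothelial, erythroid, macrophage, imprinted, chromatin regulators, senescence barrier and housekeeping. Of 336 listed symbols 331 matched the annotation, 5 of them by an older name; Sox1, Cebpd, Kcnq1ot1, Peg13 and Kmt2d did not. The rule for older names was tightened after first results had been seen, which dropped Kmt2d and matched Kmt2b; the number of list and mark pairs past the threshold stayed at 15 of 48. The p of a list's share of marked members was adjusted by Benjamini-Hochberg over the 48 pairs of list and mark. Its difference was ranked among 10000 random lists of genes marked in as many libraries. Genes are named by a fixed rule: per mark and direction the 10 called genes with the largest difference of mean covered percent (ties alphabetical), up to 4 members per list and mark with the largest difference in marked libraries, the members separating ESC from all lines, Pou5f1, Nanog, Sox2, Klf4 and Myc everywhere, and up to 5 genes per mark and direction that set ESC apart. The groups, tests, gene lists, naming rule and alternative settings were chosen before the data were examined. Afterwards 5 settings were added (the share of ESC bases covered, centring on the log2 scale, and leaving out both lines of prefix 3 or of prefix 1, and blocks of origin and title prefix).

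The alternative settings were the same number of highest peaks in every library of a mark (7085 for H3K27me3, 22708 for H3K4me3 and 97337 for H3K4me2), peaks at or above the median score of all peaks of the mark, peaks less than 3 kb apart joined, windows of 1 kb or 5 kb, and at least 500 bp covered. Further ones were genes marked in 1 to 11 libraries tested, limma on the covered percent, a Jaccard index over merged regions, ESC added to the lines, no sex chromosomes or unplaced sequence, and each library left out in turn. The blocks held 1 somatic sample and its 2 lines of the same origin and prefix, which allows 81 arrangements and a smallest p of 0.0123; limma was also run with these 4 blocks. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1, R 4.3.3 and limma 3.58.1.

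The procedures were tested on simulated data. Overlaps equalled those of bedtools in 6 pairs of lists and 38280 promoter windows, and 5.3% of 2000 draws without an effect fell below the threshold of the permutation test. The promoter test was less sensitive than intended: with 200 changed genes marked in 95% of libraries of one class and 5% of the other, it called 56.5% of them for H3K4me3 but 0% for H3K27me3 and 0% for H3K4me2. This follows from its smallest p. Unless many partly separated genes add up, no gene is called until about 4.04% of the tested genes separate the classes completely. That took 384 genes for H3K27me3, 106 for H3K4me3 and 119 for H3K4me2, while 2973, 350 and 672 genes did so in the data. With 2000 such changed genes, 54.9%, 87.95% and 87.7% were called for H3K27me3, H3K4me3 and H3K4me2, and none in the wrong direction. In every simulated setting that made calls, the false share of calls was at most 1.38%. The simulated libraries were drawn independently and without a difference in depth or enrichment between classes. That share therefore does not cover calls made by such a difference in the data. A missing call is therefore not evidence that a promoter was alike in both classes. In limma, a shift of 60 percentage points was called in 63.5%, 89.5% and 93.5% of 200 changed genes of the same marks.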

Results

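The data were 39 peak lists, 1 for each of H3K27me3, H3K4me3 and H3K4me2 in R1 ESC (strain 129, passage 20 to 22), 8 iPSC lines (passage 10 to 12), 2 APC samples and 1 MEF sample (passage 1) and 1 freshly isolated HPC sample. The lines were 1-MEF-iPSC-37 and 1-MEF-iPSC-42, 2-APC-iPSC-4 and 2-APC-iPSC-32, 2-HPC-iPSC-16 and 2-HPC-iPSC-18, and 3-APC-iPSC-3 and 3-APC-iPSC-9; the somatic samples were 1-MEF, 2-APC, 2-HPC and 3-APC. H3K27me3 lists held 7085 to 72824 peaks, H3K4me3 lists 22708 to 77797 and H3K4me2 lists 97337 to 160839. Read depth is unknown. The series title concerns sequentially reprogrammed iPSC and modifications that go with lower pluripotency; no measure of pluripotency stands in the labels, so lines were not compared by it. Coordinates are on mm9.

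The first comparison asked how H3K27me3 differed between iPSC lines and somatic cells. The promoters of Pou5f1 (chromosome 17, 35642982 to 35647721), Nanog (chromosome 6, 122657507 to 122664651) and Sox2 (chromosome 3, 34548927 to 34551383), the core transcription factors of pluripotent cells, were each covered over 100% ± 0 of the window in the somatic samples (SD, n = 4) and 0% ± 0 in the lines (SD, n = 8), with no coverage in ESC. Among the 29 pluripotency genes 14 fell, none rose, 6 were not called and 9 could not be tested. The growth factor gene Fgf4 and the RNA-binding protein gene Lin28a were also marked in 4 of 4 somatic samples and 0 of 8 lines. The share of this list under H3K27me3 was 21.1% ± 7.70 in the lines and 78.4% ± 4.34 in the somatic samples (difference -57.3 points, exact permutation p = 0.00202, Benjamini-Hochberg adjusted p = 0.00808); ESC had 20.7%. Random lists of genes marked in as many libraries had a mean difference of -49.3 points, and the list ranked at their percentile 6.85 (low percentiles are the largest falls). Over all genes 5067 of 9480 tested promoters fell. Epithelial genes fell likewise, from 91.7% ± 2.38 in somatic samples to 39.3% ± 4.93 in lines (SD, n = 4 and 8; exact permutation, Benjamini-Hochberg adjusted p = 0.00808), a difference of -52.4 points against -42.1 in random lists (percentile 1.62). In that list 9 of 21 genes fell, among them the adhesion genes Cdh1 (chromosome 8, 109127251 to 109194146) and Epcam (chromosome 17, 88035319 to 88050446), each covered over 100% ± 0 of the window in 4 somatic samples and 0% ± 0 in 8 lines.

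Calls among mesenchymal genes were in the other direction. Of 26 members 8 rose, none fell, 3 were not called and 15 could not be tested. Zeb1 (chromosome 18, 5591858 to 5775465), a repressor of epithelial genes, was marked in 8 of 8 lines and 0 of 4 somatic samples, over 54.8% ± 9.05 of its window in the lines. Its relative Zeb2, the collagen gene Col1a2 and the fibrillin gene Fbn1 were marked in 8 of 8 lines and only in 2-HPC among the somatic samples. The list share was 65.9% ± 5.61 in lines and 36.5% ± 32.1 in somatic samples, a difference that missed the threshold (exact permutation p = 0.0182, Benjamini-Hochberg adjusted p = 0.0513). Within the somatic class the share was 84.6% in 2-HPC, 19.2% in 1-MEF, 19.2% in 2-APC and 23.1% in 3-APC. Random lists had a mean difference of -9.05 points, against 29.3 for this list (percentile 100).

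Other lists with less H3K27me3 in the lines were imprinted genes (60.4% ± 2.88 against 79.9% ± 5.73; 6 of 36 fell), chromatin regulators (17.8% ± 3.92 against 46.1% ± 8.99; 5 of 19 fell and 1 rose), adipogenic genes (51.5% ± 8.17 against 73.5% ± 5.88; 4 of 17 fell) and endothelial genes (63.5% ± 9.90 against 87.5% ± 4.81; 2 of 12 fell). Erythroid genes (50% ± 13.3 against 91.7% ± 5.56; 3 of 9 fell), macrophage genes (15.9% ± 6.43 against 56.8% ± 8.70; 2 of 11 fell) and housekeeping genes (7.5% ± 3.78 against 18.8% ± 2.5; 3 of 20 fell) were also lower. Values are mean ± SD over 8 lines and 4 somatic samples, and the exact permutation tests gave Benjamini-Hochberg adjusted p = 0.0149 for housekeeping genes and 0.00808 for the rest. Against random lists of genes marked in as many libraries these falls were not extreme. The percentiles were 50.3 for imprinted genes, 61.3 for chromatin regulators, 58.0 for adipogenic, 19.09 for endothelial, 16.9 for erythroid, 59.0 for macrophage and 82.0 for housekeeping genes. Among the members that fell were the imprinted genes Rtl1, Mirg and Rian of the Dlk1-Dio3 cluster, the adipokine gene Adipoq, the Polycomb subunit gene Cbx7, the erythroid factor gene Klf1 and the complement gene C1qb. Of the housekeeping genes that fell, Pgk1 and Hprt lie on the X chromosome, where somatic samples had 70.6% of promoters marked and lines 16.3%. The remaining one, Psmb2, lies on chromosome 4. List shares were not tested without the X chromosome. Tet3, which encodes a methylcytosine dioxygenase, was the chromatin regulator that rose, in 8 of 8 lines against 0 of 4 somatic samples. Haematopoietic genes (69.0% ± 6.38 against 81.0% ± 12.7; 1 rose and 4 fell) and senescence barrier genes (50% ± 6.68 against 34.4% ± 12.0) did not pass, with Benjamini-Hochberg adjusted p = 0.155 and 0.0808 by exact permutation; the cell cycle inhibitor gene Rb1 in the latter rose in 8 of 8 lines. Germline (73.4% ± 13.7 against 81.3% ± 5.10), endoderm mesoderm (92.5% ± 2.67 against 95% ± 0), hox (100% ± 0 against 94.2% ± 6.74) and neural factor lists (100% ± 0 in both) gave no difference past the threshold, with none of their members called.

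Over all genes, 5067 promoters fell and 480 rose of 9480 tested (Fisher's exact test, Benjamini-Hochberg). The promoters of Dok1 and Gab2, which encode signalling adaptors, and of Apbb1ip, which encodes a Rap1 effector, were among those covered over 100% ± 0 of the window in 8 lines and 0% ± 0 in 4 somatic samples. H3K27me3 covered 196 Mb ± 104 in the lines, 909 Mb ± 67.1 in the somatic samples (SD, n = 8 and 4) and 241 Mb in ESC, a log2 difference of -2.35 (exact permutation p = 0.00202). Peak number was 18473 ± 11048 against 56712 ± 17686 (log2 difference -1.75, exact permutation p = 0.00404, n = 8 and 4), with 18413 in ESC. In every list the counts adjusted over the list alone equalled those over all genes tested. With the same number of highest peaks in every library, 1083 promoters rose and 2229 fell (32.7% higher, against 8.65% with all peaks), of which 386 and 1566 were shared with the calls above. At that setting the adipogenic, endothelial, imprinted and chromatin regulator lists no longer differed, with Benjamini-Hochberg adjusted p = 0.933, 1, 1 and 0.388 (exact permutation), and Gata1, Cldn4, Adipoq, Klf1, Mirg and Cbx7 were marked in too few libraries to be tested. The macrophage difference was -25 points there (-40.9 with all peaks) and the housekeeping difference -6.25 (-11.3 with all peaks), both past the threshold. The germline list turned from -7.81 to 28.9 points and passed there (exact permutation, Benjamini-Hochberg adjusted p = 0.00746).

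**Figure D1:**
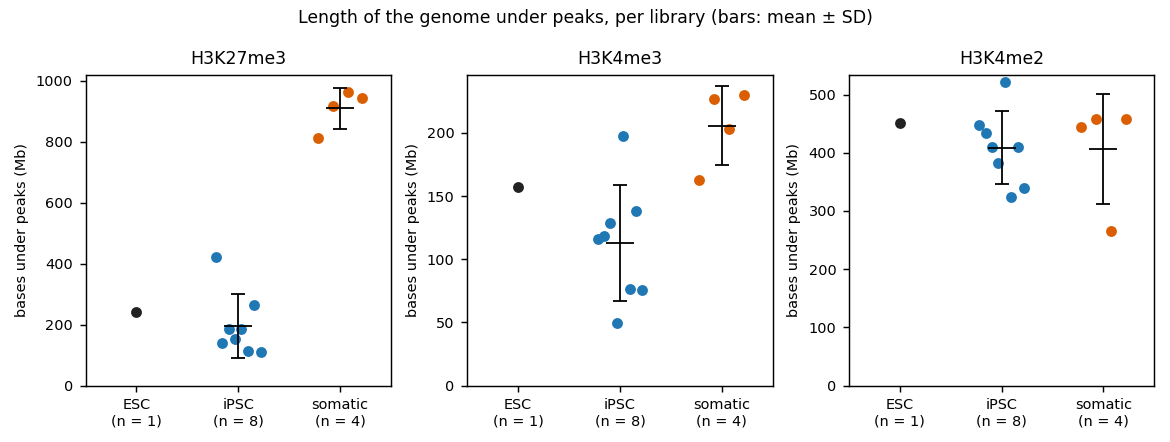
Length of the genome under peaks in Mb (vertical axis) for each library of the 3 marks, by class; points are libraries, horizontal bars the mean and whiskers the SD of the 8 iPSC lines and 4 somatic samples. For H3K27me3 the somatic samples lay between 813 and 964 Mb and the lines between 109 and 422 Mb.

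The second comparison asked the same of H3K4me3. Nanog was covered over 94.9% ± 6.53 of its window in the 8 lines and 0% ± 0 in the 4 somatic samples, and Pou5f1 over 96.9% ± 8.90 against 1.29% ± 2.59 (SD; Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0150 and 0.0436). Dppa2 (chromosome 16, 48310590 to 48319836) and Dppa4 (chromosome 16, 48283848 to 48294405), neighbouring genes expressed in pluripotent cells and germ cells, had 81.9% ± 11.0 and 79.8% ± 13.8 coverage in 8 lines and 0% ± 0 in 4 somatic samples. In all, 7 of 29 pluripotency genes rose and 22 could not be tested, and the share marked was 100% ± 0 in lines against 75.9% ± 4.88 in somatic samples (SD, n = 8 and 4; exact permutation, Benjamini-Hochberg adjusted p = 0.00808). Sox2, Klf4 and Myc, the remaining genes followed in every library, were covered over 100% of the window in all 13 libraries. Of 16 germline genes 9 rose, none fell and 2 were not called, with a share of 87.5% ± 15.7 against 18.8% ± 11.4 (SD, n = 8 and 4; exact permutation, Benjamini-Hochberg adjusted p = 0.00808). Both lists stood at percentile 100 of random lists. Germline examples were Tex19.1 (69.2% ± 20.9 of the window in lines), the RNA helicase gene Ddx4 (51.1% ± 10.9) and the transcription factor gene Sohlh2 (49.7% ± 13.4), each at 0% ± 0 in the 4 somatic samples.

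Macrophage genes fell in H3K4me3, 4 of 11 being called lower, and their share was 30.7% ± 9.64 in lines against 75% ± 32.7 in somatic samples (SD, n = 8 and 4; exact permutation, Benjamini-Hochberg adjusted p = 0.0453), at percentile 3.60 of random lists. With arrangements only within blocks of origin and prefix this call was lost (exact permutation, Benjamini-Hochberg adjusted p = 0.0988). Csf1r (chromosome 18, 61265226 to 61291803), the receptor gene for a macrophage growth factor, was covered over 71.1% ± 10.5 in 4 somatic samples and 0% ± 0 in 8 lines. Within the somatic class, macrophage genes were marked at 100% in 2-APC, 90.9% in 3-APC, 81.8% in 2-HPC and 27.3% in 1-MEF. ESC had 27.3%, 1-MEF-iPSC-37 had 36.4% and 1-MEF-iPSC-42 had 45.5%, so the list share did not fall from 1-MEF to its lines. The macrophage surface gene Emr1 (also called Adgre1) and the leukocyte gene Ptprc were marked in both APC samples and in 2-HPC and not in 1-MEF. Beside these, haematopoietic genes had 75.9% ± 10.1 against 84.5% ± 17.5 (1 rose and 3 fell), adipogenic genes 70.6% ± 5.45 against 79.4% ± 7.59 (the fatty acid binding gene Fabp4 fell) and mesenchymal genes 88.0% ± 5.97 against 97.1% ± 5.77 (the proteoglycan gene Lum fell). The T cell receptor complex gene Cd3e was the haematopoietic gene that rose, over 42.6% ± 11.3 in 8 lines against 0% ± 0. Erythroid (47.2% ± 5.14 against 58.3% ± 27.8), endothelial (68.8% ± 13.2 against 83.3% ± 15.2), imprinted (88.5% ± 0.982 against 89.6% ± 4.17; Rtl1 fell), epithelial (99.4% ± 1.68 against 96.4% ± 4.56), endoderm mesoderm (99.4% ± 1.77 against 96.3% ± 4.79) and senescence barrier lists (98.4% ± 4.42 against 100% ± 0) did not pass. Hox, neural factor, chromatin regulator and housekeeping lists were marked at 100% ± 0 in both classes. Counts adjusted over the list alone were the same, except that Lum and Fabp4 were then not called.

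Over all genes 377 promoters rose and 709 fell of 2603 tested (Fisher's exact test, Benjamini-Hochberg). These 1086 calls became 351 to 606 when any of 10 single libraries was left out, that is, any but 3-APC-iPSC-3 or 1-MEF-iPSC-42. Promoters that fell with the largest difference included those of Uba7, which encodes an activating enzyme for ISG15 (93.1% ± 8.95 of the window in 4 somatic samples), and of Tlr4, the receptor gene for bacterial lipopolysaccharide (91.4% ± 6.13), both at 0% ± 0 in 8 lines. H3K4me3 covered 113 Mb ± 46.0 in lines and 206 Mb ± 31.0 in somatic samples (SD, n = 8 and 4; log2 difference -0.97, exact permutation p = 0.0141), with 157 Mb in ESC. Peak number was 41521 ± 14097 against 64466 ± 12195 (log2 difference -0.69, exact permutation p = 0.0283, n = 8 and 4) and 57823 in ESC. That difference missed the threshold without any 1 of 3-APC-iPSC-3, 2-APC-iPSC-4, 3-APC-iPSC-9, 2-APC, 2-HPC or 3-APC (exact permutation p from 0.0515 to 0.103), with peaks at or above the median score (exact permutation p = 0.101) and without both prefix 3 lines (exact permutation p = 0.0762). The number of genes marked was 17324 ± 760 against 17922 ± 434 (exact permutation p = 0.182, n = 8 and 4). The balance of calls depended on the peaks used: with the same number of highest peaks 761 promoters rose and 448 fell (62.9% higher, against 34.7% with all peaks; 250 and 185 shared), and without both prefix 3 lines 306 rose and 189 fell (61.8% higher). At the same number of highest peaks the macrophage list missed the threshold (exact permutation, Benjamini-Hochberg adjusted p = 0.0513), and Ddx4, Fabp4, Lum and Rtl1 were not called. The germline difference was 39.1 points there (68.8 with all peaks) and the pluripotency difference 47.4 (24.1 with all peaks), both past the threshold. Epithelial (17.9 points), neural factor (11.8) and endoderm mesoderm lists (21.3) were higher in lines there (exact permutation, Benjamini-Hochberg adjusted p = 0.00746 for each).

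The third comparison concerned H3K4me2. Nanog was covered over 100% ± 0 of its window in 8 lines and 0% ± 0 in 4 somatic samples. Dppa4 was covered over 98.0% ± 5.24 against 0% ± 0 (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00883 for both). Pluripotency genes were marked at 100% ± 0 in lines and 84.5% ± 1.99 in somatic samples, with 4 of 29 called higher and 25 not testable. Germline genes were marked at 96.9% ± 3.34 against 40.6% ± 14.9, with 8 of 16 called higher (SD, n = 8 and 4; exact permutation, Benjamini-Hochberg adjusted p = 0.00808 for both lists). Among random lists they stood at percentiles 91.6 and 99.7. Stra8, a gene induced by retinoic acid at the onset of meiosis, was covered over 93.9% ± 4.03 in 8 lines and 0% ± 0 in 4 somatic samples. Macrophage genes had 61.4% ± 4.21 against 86.4% ± 17.4, with 3 of 11 called lower, Csf1r, Emr1 and C1qb (SD, n = 8 and 4; exact permutation, Benjamini-Hochberg adjusted p = 0.0453). By sample that share was 100% in 2-APC, 100% in 3-APC, 81.8% in 2-HPC and 63.6% in 1-MEF. It was 72.7% in ESC and 63.6% in each MEF line, so it did not fall from 1-MEF to its lines.

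Haematopoietic genes went both ways in H3K4me2, with 4 higher, among them Cd3e and the erythroid factor gene Gata1, and 2 lower, the leukocyte gene Cd53 and the lysozyme gene Lyz2; the share was 90.1% ± 1.22 against 86.2% ± 10.2. Imprinted (91.7% ± 0 against 88.2% ± 10.7; Rtl1 fell), adipogenic (89.0% ± 2.08 against 89.7% ± 2.94; the fatty acid transporter gene Cd36 fell), endothelial (90.6% ± 2.95 against 95.8% ± 4.81; Emcn fell) and erythroid lists (69.4% ± 7.86 against 75% ± 19.0) did not pass. Neither did mesenchymal (97.1% ± 1.78 against 98.1% ± 3.85), endoderm mesoderm (100% ± 0 against 96.3% ± 2.5), hox (100% ± 0 against 98.1% ± 3.85), neural factor (100% ± 0 against 98.7% ± 2.63) and epithelial lists (100% ± 0 against 98.8% ± 2.38). Chromatin regulator, senescence barrier and housekeeping lists were at 100% ± 0 in both classes, and counts adjusted over the list alone were the same throughout. Over all genes 994 promoters rose and 579 fell of 2937 tested (Fisher's exact test, Benjamini-Hochberg). These 1573 calls became 740 without 3-APC, 763 without 2-APC and 795 without 1-MEF. Of the genes tested for both marks 232 rose in H3K4me3 and H3K4me2 (126 for independent lists) while 0 rose in H3K4me3 and fell in H3K4me2. Covered length was 409 Mb ± 62.7 in lines, 406 Mb ± 94.4 in somatic samples (SD, n = 8 and 4; log2 difference 0.03, exact permutation p = 0.869) and 450 Mb in ESC. Peak number was 133273 ± 14501 against 137011 ± 27709 (log2 difference -0.02, exact permutation p = 0.871, n = 8 and 4) with 139688 in ESC. The macrophage call was lost with the same number of highest peaks, with windows of 1 kb or 5 kb and with at least 500 bp covered (exact permutation, Benjamini-Hochberg adjusted p = 0.482, 0.312, 0.128 and 0.139), and within blocks of origin and prefix (0.0988). With the same number of highest peaks Emr1, C1qb and the endothelial sialomucin gene Emcn were marked in too few libraries to be tested, while Csf1r stayed lower. The pluripotency difference was 28.4 points there, against 15.5 with all peaks. The endoderm mesoderm list was 8.75 points higher in lines with the same number of highest peaks (exact permutation, Benjamini-Hochberg adjusted p = 0.00746).

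**Figure D2:**
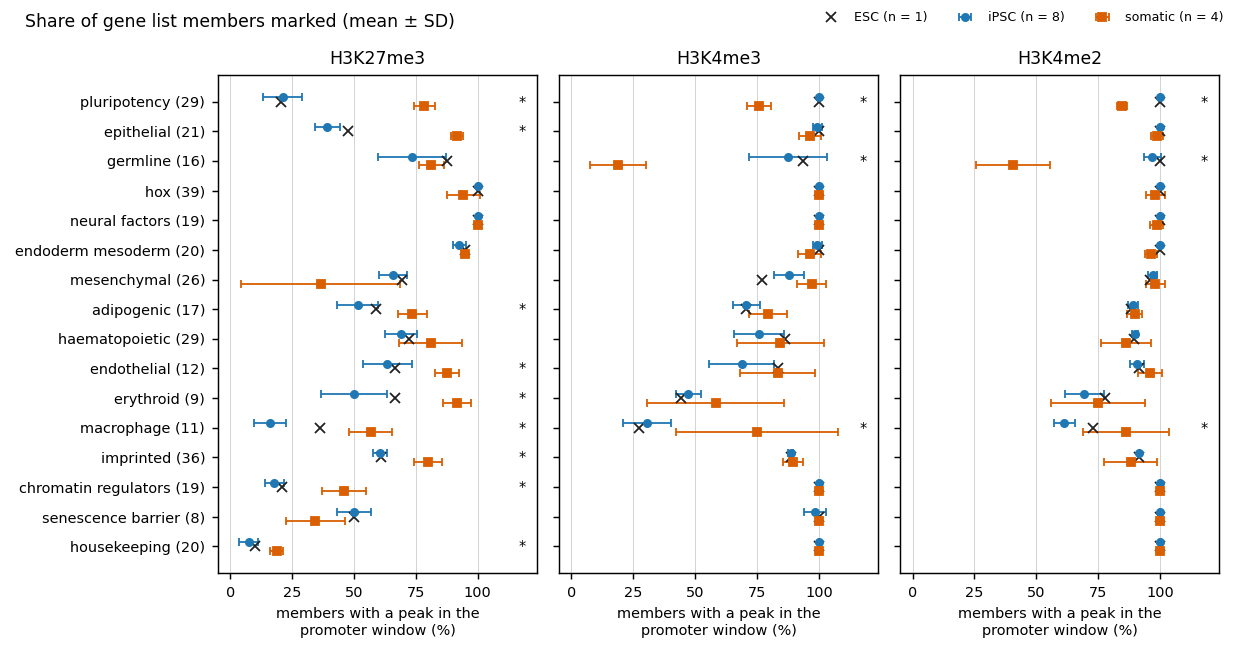
Share of the members of each gene list with a peak in the promoter window, in percent (horizontal axis), with the number of genes in brackets; circles are the mean of 8 iPSC lines, squares the mean of 4 somatic samples, whiskers the SD, crosses the ESC library, and asterisks a Benjamini-Hochberg adjusted p below 0.05 by exact permutation. Pluripotency genes stood at 21.1% in lines and 78.4% in somatic samples for H3K27me3, and at 100% and 75.9% for H3K4me3.

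**Figure D3:**
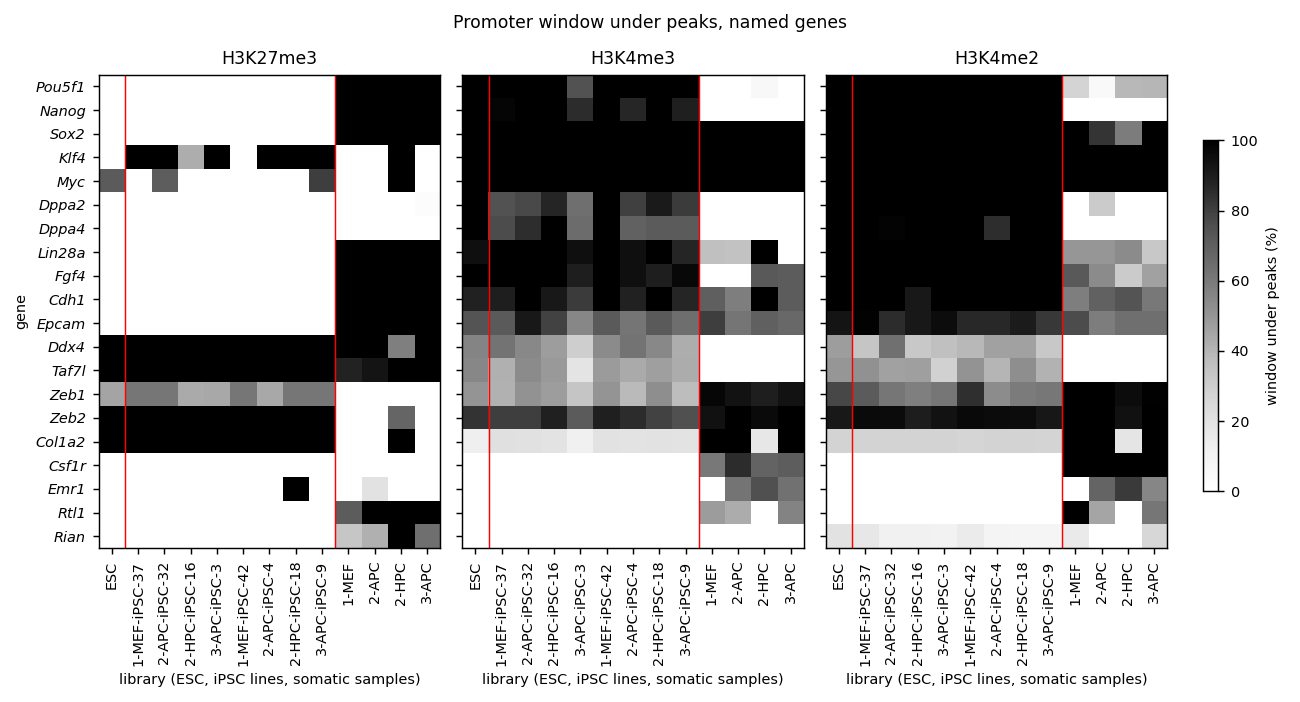
Share of the promoter window under peaks (grey scale, 0 to 100%) for named genes, by library and mark; red lines part the ESC library, the 8 iPSC lines and the 4 somatic samples. Nanog was at 100% in H3K27me3 in the somatic samples only, and at 100% in H3K4me2 in the pluripotent libraries only.

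Promoters with both H3K4me3 and H3K27me3 were counted next. Bivalent genes numbered 6247 ± 986 in lines, 9760 ± 892 in somatic samples (SD, n = 8 and 4; difference -3513, exact permutation p = 0.00202) and 7025 in ESC. Genes with H3K27me3 alone numbered 974 ± 508 in lines against 3855 ± 111 in somatic samples (exact permutation p = 0.00202, n = 8 and 4). Of the H3K27me3 genes 87.1% ± 4.16 were bivalent in a line and 71.6% ± 1.78 in a somatic sample. Of the genes bivalent in ESC, lines kept 80.9% ± 8.62 and somatic samples 75.7% ± 5.32 (difference 5.22 points, exact permutation p = 0.291, n = 8 and 4). Both results turned on the number of peaks used: with the same number of highest peaks the difference in bivalent genes was -16.5 (exact permutation p = 0.964), and lines kept 31.8 points more of the ESC bivalent genes (exact permutation p = 0.00202).

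The next comparison asked how far each library shared the marked regions of ESC. For H3K27me3 the Jaccard index with ESC was 0.432 ± 0.0570 in lines and 0.182 ± 0.0116 in somatic samples (SD, n = 8 and 4; exact permutation p = 0.00202), for H3K4me3 0.554 ± 0.125 against 0.307 ± 0.0197 (exact permutation p = 0.0121). For H3K4me2 it was 0.679 ± 0.0312 against 0.296 ± 0.0132 (exact permutation p = 0.00202). Of the bases a line marked, 73.3% ± 13.8 for H3K27me3, 89.4% ± 9.36 for H3K4me3 and 85.7% ± 4.65 for H3K4me2 lay in ESC peaks, against 19.5% ± 1.34, 41.9% ± 5.20 and 49.4% ± 6.34 in somatic samples (exact permutation p = 0.00202 for each, n = 8 and 4). For H3K27me3, ESC peaks covered 241 Mb and somatic lists 813 to 964 Mb. Most bases of a somatic list could therefore not lie in ESC peaks, which caps both that share and its Jaccard index. The share of ESC bases that a library covered gave another order for H3K27me3, 54.8% ± 14.2 in lines and 73.6% ± 2.72 in somatic samples (exact permutation p = 0.0323, n = 8 and 4). For H3K4me3 that share was 61.7% ± 18.4 against 54.0% ± 2.33 (exact permutation p = 0.436, n = 8 and 4). Among somatic samples the MEF and APC lists were closer to each other than to HPC, with mean Jaccard indices of 0.530 and 0.342 for H3K4me3 and 0.613 and 0.292 for H3K4me2.

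Whether a line shared more regions with its own cell type of origin was asked next. MEF, APC and HPC lines showed no such excess. The own-origin entry was 0.000376 for H3K27me3 (exact permutation p = 0.826, 8 lines) and -0.00269 for H3K4me2 (exact permutation p = 0.240). For H3K4me3 it was below 0, at -0.00633 (exact permutation p = 0.00714, 8 lines). That value lost the threshold over merged regions (-0.00646, exact permutation p = 0.0643). It was -0.00286 without 1-MEF and -0.00673 without 2-HPC (exact permutation p = 0.0667 for both). Lines of the missing type drop out there, and 0.0667 is the smallest p the lines left allow. Neither setting could therefore pass the threshold.

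The prefix comparison asked whether similarity to ESC changed with the number that opens the line's title. For H3K4me3 the mean Jaccard index was 0.643 in the 2 lines of prefix 1, 0.593 in the 4 of prefix 2 and 0.388 in the 2 of prefix 3. Spearman's rho was -0.849 and Pearson's r -0.768, both with exact permutation p = 0.0143 and Benjamini-Hochberg adjusted p = 0.0429 over 3 marks (n = 8). The number of H3K4me3 peaks also fell with the prefix (rho -0.772, exact permutation p = 0.0381). The share of a line's own bases in ESC peaks had rho 0.694 (exact permutation p = 0.0762), and by the share of ESC bases covered the call was lost (rho -0.694, exact permutation p = 0.0762). For H3K27me3 rho was -0.309 and r -0.305 (exact permutation p = 0.510 and 0.471), and for H3K4me2 rho was -0.694 and r -0.628 (exact permutation p = 0.0762 and 0.105). Without the lines of prefix 1 the H3K4me3 r was -0.793, and without those of prefix 3 it was -0.358. Leaving out 3-APC-iPSC-3 or 3-APC-iPSC-9 gave rho -0.777 (exact permutation p = 0.0571). Prefix 1 held MEF lines only and prefix 3 APC lines only. Within APC lines the values were 0.633 and 0.463 for prefix 2 and 0.315 and 0.461 for prefix 3 (exact permutation p = 0.333, the smallest possible for 2 against 2).

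Last, ESC was set against all 8 lines. Klf4, a reprogramming factor, carried H3K27me3 in 7 of 8 lines, in 1 of 4 somatic samples and not in ESC. In H3K4me2, Trim34b (chromosome 7, 111448744 to 111485423), a member of the tripartite motif family, was marked over 75.6% ± 0.930 in the 8 lines (SD) and 0% in ESC and in the 4 somatic samples. Among members of the gene lists, H3K27me3 marked 6 in ESC and in 0 of 8 lines. In ESC the transcription factor gene Cebpb was covered over 100% of its window (marked in 1 of 4 somatic samples), the tight junction gene Marveld2 over 82.1% (2 of 4), the complement gene C1qa over 50.8% (4 of 4) and the amino acid transporter gene Slc38a4 over 19.7% (2 of 4). The collagen gene Col3a1 (1 of 4) and the neutrophil elastase gene Elane (4 of 4) were covered in ESC over only 1.99% and 1.10%, and counted as marked because 1 bp was enough. The receptor tyrosine kinase gene Kit was marked in 8 of 8 lines and 4 of 4 somatic samples and not in ESC. Promoters marked in ESC alone among the pluripotent libraries numbered 257 for H3K27me3, 90 for H3K4me3 and 70 for H3K4me2, and those marked in all lines but not in ESC 29, 2 and 34. By the sum of both, ESC ranked 4, 3 and 4 of the 9 pluripotent libraries, so that a line set against the others gave more in each mark (for H3K27me3, 773 in 1-MEF-iPSC-37). Without 1-MEF-iPSC-42 the sum was 347 for H3K4me3 (92 with it) and 182 for H3K4me2 (104 with it), and ESC ranked 2 and 1. There was 1 ESC library per mark and no test.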

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

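The tests with the same number of highest peaks for covered length and for the title prefix, the Hox, Y-linked and APC tests, the counts of splits without adjustment, and the lists of values far from their group were chosen after the results had been seen; the other tests below were chosen before.

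H3K27me3 covered less of the genome in the 8 lines than in the 4 somatic samples (log2 difference -2.35). With the same number of highest peaks the difference was -1.64 (exact permutation p = 0.00202). That setting sets all 7085 peaks of 3-APC-iPSC-9 against only the highest-scoring ones of somatic lists holding 34272 to 72824. It compares the lengths of unlike parts of the lists, so it cannot exclude more calling in the somatic libraries as the cause. X-linked domains were not the whole cause, since the difference was -2.25 without the sex chromosomes and unplaced sequence (exact permutation p = 0.00202). Weaker enrichment or fewer reads in the iPSC libraries and a difference between pluripotent and somatic chromatin cannot be told apart, because neither reads nor enrichment over input were analysed. Hox promoters, under H3K27me3 in 100% of cases in lines and 94.2% in somatic samples, do not decide it.

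H3K4me3 similarity to ESC was lower in lines of a higher title prefix (rho -0.849). With the same number of highest peaks rho was -0.772 (exact permutation p = 0.0381, not adjusted over the 3 marks). The share of a line's own bases lying in ESC peaks went the other way (rho 0.694, exact permutation p = 0.0762). Only the prediction for that share was written before its result, and fewer peaks as the cause predicted no fall in it. The 2 values point different ways, so fewer peaks in the prefix 3 lines stay open as a cause. Prefix and cell type of origin cannot be told apart, because within APC lines prefix 3 minus prefix 2 was -0.160 and 2 against 2 lines allow no p below 0.333 (exact permutation). Whatever the prefix stands for stays open and untested.

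The X chromosome held 8.85% ± 1.54 of the H3K27me3 length in 4 somatic samples and 2.07% ± 0.265 in 8 lines (SD; exact permutation p = 0.00202). Weak regions in the somatic libraries were not the whole cause, since a difference of 4.71 points stood with the same number of highest peaks (6.95% against 2.24%, exact permutation p = 0.00202). Somatic samples from female animals alone are excluded, because 4 of 4 had H3K4me3 at all 4 of the Y-linked promoters Ddx3y, Eif2s3y, Kdm5d and Uty, as had 9 of 9 pluripotent libraries. A mixture of sexes in the somatic samples was not tested and stays open.

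Other splits of the 12 libraries into 8 and 4 did not give as many promoter calls. Of 100 splits, 1 (the real one) gave 5547 calls for H3K27me3, 1 gave 1086 for H3K4me3 and 1 gave 1573 for H3K4me2, and the highest other split gave 0 in each mark. The adjustment makes no call until enough promoters separate 2 groups completely or nearly so, which holds other splits near 0, so this count alone decides little. Without adjustment, the real split had 5547, 1086 and 1573 promoters with a p under 0.05 (Fisher's exact test) and the highest of the other 99 had 1272, 286 and 507. The real split thus ranked 1 of 100 in each mark, and the splits drawn allow no stronger statement. It also parts the libraries by H3K27me3 covered length (813 to 964 Mb in somatic samples, 109 to 422 Mb in lines), so the rank does not separate class from list size.

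A library lay far from the others of its group, by its gap to the nearest one relative to the range, in 41 of 176 groups looked at (23.3%); chance marks about 1 in 20 groups. The 4 APC lines also stand among the 8 lines, and shares of short lists take few values. Where the other libraries of a group tie, a single gene is enough for a flag, so the rate of 1 in 20 does not hold there. In 2-HPC among 4 somatic samples, H3K4me2 covered 265 Mb and 58.8% of its bases lay in ESC peaks. The same library's list shares were, for H3K27me3, mesenchymal 84.6% and haematopoietic 62.1%, and for H3K4me3, mesenchymal 88.5%, erythroid 100% and imprinted 83.3%. For H3K4me2 they were hox 92.3%, neural factors 94.7%, mesenchymal 92.3% and imprinted 72.2%. In 1-MEF the H3K4me3 Jaccard index with ESC was 0.336, the H3K27me3 shares were epithelial 95.2% and housekeeping 15%, and the H3K4me2 share of endoderm mesoderm was 100%. In 3-APC the H3K27me3 shares were adipogenic 64.7% and erythroid 100%, and the H3K4me2 epithelial share was 95.2%. In 2-APC the H3K4me2 adipogenic share was 94.1%.

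Among the lines, 3-APC-iPSC-3 had H3K4me3 shares of germline 50%, endoderm mesoderm 95% and senescence barrier 87.5%, and an H3K4me2 endothelial share of 83.3%, each far from both the 8 lines and the 4 APC lines. The H3K4me3 list of this line was the shortest of the mark (22708 peaks, 49.9 Mb), which can lower such shares. In H3K4me2 the germline share of the same line was 100%. Its H3K27me3 pluripotency share of 17.2% was far from the other APC lines. In 3-APC-iPSC-9 the H3K4me3 shares were epithelial 95.2% and imprinted 86.1%, against both groups, and among APC lines the H3K4me3 median peak width was 2.25 kb, the H3K27me3 mesenchymal share 57.7%, the H3K4me2 mesenchymal share 100% and the H3K4me2 macrophage share 54.5%. Among APC lines 2-APC-iPSC-32 had an H3K27me3 chromatin regulator share of 21.1% and 2-APC-iPSC-4 an H3K27me3 senescence barrier share of 37.5%. Among the 8 lines, 1-MEF-iPSC-42 had an H3K4me3 adipogenic share of 82.4%, 2-HPC-iPSC-16 an H3K4me2 adipogenic share of 94.1% and 1-MEF-iPSC-37 an H3K4me2 haematopoietic share of 93.1%.

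In 29 of 222 contrasts over 74 measures, lines minus their own somatic type moved one way in every line of one origin and the opposite way in every line of another. These differences were not tested, and each origin has 1 or 2 somatic samples. Values below are the first origin minus the second. MEF minus HPC was, for H3K4me3, -0.6 kb in median peak width, 1311 in genes marked, and in list shares -17.3 points mesenchymal, 37.9 haematopoietic, 41.7 endothelial, 63.6 macrophage and -8.33 imprinted. For H3K27me3 it was 67.3 mesenchymal and -25.9 haematopoietic, and for H3K4me2 -0.6 kb in width, 25.9 haematopoietic and -22.2 imprinted. APC minus HPC was, for H3K4me3, -0.488 kb in width, 0.819 points in the X share of covered length, -21.2 mesenchymal and -9.03 imprinted. For H3K27me3 it was 59.6 mesenchymal and -35.3 haematopoietic. For H3K4me2 it was -54909 in peak number, -234 Mb in covered length, -0.488 kb in width, 15.5 haematopoietic and -20.8 imprinted. MEF minus APC was, for H3K4me3, 2064 in genes marked, 46.6 points haematopoietic and 84.1 macrophage, for H3K4me2 34195 in peak number and 128 Mb in covered length, and for H3K27me3 28.1 germline.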

How the results depend on the processing

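The share of ESC bases covered, centring on the log2 scale and leaving out both lines of prefix 3 or of prefix 1, and blocks of origin and title prefix, were chosen after seeing the data; the other settings were chosen before. No paired analysis was possible because the groups compared within a mark share no line number; blocks of 1 somatic sample and its 2 lines of the same origin and prefix were used instead. The blocks ended the macrophage list calls for H3K4me3 and H3K4me2 (exact permutation, Benjamini-Hochberg adjusted p = 0.0988) and kept the other 13 list calls. They changed no other call of the permutation tests run with them. Limma with these blocks called 7161, 1536 and 1874 promoters for H3K27me3, H3K4me3 and H3K4me2, against 7083, 1479 and 1870 without them. The calls shared by both were 6984, 1447 and 1826. Log2 H3K27me3 peak number (-2.14 to -1.32) and covered length (-2.57 to -1.64), H3K4me3 covered length (-1.15 to -0.57) and H3K4me2 similarity to ESC (0.337 to 0.412) kept their direction and side of the threshold in all 19 settings run for each. Depth is unknown, so no setting separates it from the class. Where no cause is named below, the cause was not tested.

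With the same number of highest peaks, H3K27me3 calls numbered 3312 against 5547, bivalent genes differed by -16.5 (exact permutation p = 0.964), ESC bivalent genes kept by 31.8 points (exact permutation p = 0.00202) and the H3K4me2 own-origin entry was -0.00230 (exact permutation p = 0.0167). With windows of 5 kb, ESC bivalent genes kept differed by -0.581 (exact permutation p = 0.895). With peaks at or above the median score, H3K4me3 log2 peak number was -0.60 (exact permutation p = 0.101). This cut runs across lists whose scores have scales of their own, so the value is hard to read. Over merged regions the H3K4me3 own-origin entry was -0.00646 (exact permutation p = 0.0643). With genes marked in 1 to 11 libraries tested, calls numbered 350 for H3K4me3 (46.3% higher) and 672 for H3K4me2 (75% higher, against 63.2%), since more genes were tested. By the share of ESC bases covered, similarity to ESC was -0.188 for H3K27me3 (exact permutation p = 0.0323) and 0.0768 for H3K4me3 (exact permutation p = 0.436), and Spearman's correlation with the prefix was -0.694 for H3K4me3 (exact permutation p = 0.0762) and -0.772 for H3K4me2 (exact permutation p = 0.0381). Centring on the log2 scale gave an H3K27me3 own-origin entry of -0.0113 (exact permutation p = 0.429). Limma called 555 promoters higher and 6528 lower for H3K27me3, 455 and 1024 for H3K4me3, and 995 and 875 for H3K4me2 (53.2% higher).

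With fewer samples the smallest possible p is larger. Without both lines of prefix 3, calls numbered 3016 for H3K27me3, 495 for H3K4me3 and 715 for H3K4me2 (75.4% higher), and H3K4me3 log2 peak number was -0.48 (exact permutation p = 0.0762). Without both lines of prefix 1, calls numbered 3490, 446 and 725, own-origin entries were -0.000271 for H3K27me3 (exact permutation p = 0.8) and -0.00286 for H3K4me3 (exact permutation p = 0.0667), and H3K4me2 log2 covered length was -0.0564 (exact permutation p = 0.752). For these own-origin entries 0.0667 was the smallest p the lines left allowed.

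Leaving out 1 library at a time, H3K4me3 calls ranged from 351 (without 2-APC-iPSC-32) to 1243 (without 1-MEF-iPSC-42). They were 352 without 1-MEF-iPSC-37, 352 without 2-APC-iPSC-4, 361 without 2-HPC-iPSC-16, 362 without 2-HPC-iPSC-18, 356 without 3-APC-iPSC-9, 550 without 1-MEF, 386 without 2-APC, 606 without 2-HPC and 389 without 3-APC. H3K4me2 calls ranged from 740 (without 3-APC) to 1650 (without 1-MEF-iPSC-42), with 795 without 1-MEF and 763 without 2-APC. H3K4me3 log2 peak number ranged from -0.81 to -0.57 and missed the threshold without 3-APC-iPSC-3, 2-APC-iPSC-4, 3-APC-iPSC-9, 2-APC, 2-HPC or 3-APC (exact permutation p from 0.0515 to 0.103). H3K4me2 log2 peak number ranged from -0.18 to 0.0633, above 0 without 2-APC-iPSC-4, 3-APC-iPSC-9, 2-APC or 3-APC, and log2 covered length from -0.16 to 0.10, below 0 without 1-MEF-iPSC-42 (-0.02) or 2-HPC. Spearman's correlation with the prefix ranged from -0.945 to -0.777 for H3K4me3 and from -0.850 to -0.538 for H3K4me2, where it passed the threshold without 3-APC-iPSC-3 (-0.797, exact permutation p = 0.0381) or 2-APC-iPSC-4 (exact permutation p = 0.0286). Own-origin entries ranged from -0.000271 (without 1-MEF) to 0.000812 for H3K27me3 and from -0.00752 to -0.00286 for H3K4me3. Promoters that set ESC apart ranged from 92 to 347 for H3K4me3 and from 112 to 182 for H3K4me2, both highest without 1-MEF-iPSC-42.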

Other observations

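The tests of origin below were chosen before their results were seen; the comparison with their SD over arrangements was added after, and Tsix and Xist were chosen after their values were seen.

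Tsix, the antisense transcript that represses Xist, was under H3K27me3 over 100% ± 0 of its promoter window in 4 somatic samples and 0% ± 0 in 8 lines and ESC. H3K4me3 covered 55.3% ± 16.6 of the Tsix window in the 8 lines and 0% ± 0 in the 4 somatic samples (SD; Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0150). Xist, the RNA that silences an X chromosome, had H3K27me3 over 63.2% ± 22.5 of its window in 4 somatic samples and 1.11% ± 2.09 in 8 lines (SD), and was not called. Of X-linked promoters 70.6% ± 6.24 were under H3K27me3 in somatic samples and 16.3% ± 3.86 in lines, and of autosomal promoters 51.5% ± 3.65 and 28.2% ± 5.57 (SD, n = 4 and 8; exact permutation p = 0.00202 for both).

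A hypothesis was that lines may keep marks of their own cell type of origin at promoters marked in a single somatic type and not in ESC. The own-origin entry was -0.374 points for H3K27me3 (exact permutation p = 0.479), -0.0127 for H3K4me3 (exact permutation p = 0.976) and -1.22 for H3K4me2 (exact permutation p = 0.124). Each lay below the predicted excess of 2 points by more than its SD over arrangements (0.462, 0.429 and 0.827). No own-origin excess was seen, but none is excluded. That SD describes shuffled origins and is not the error of the entry, and centring shrinks an own-origin excess.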
